A study of Homo sapiens with 6 samples.

How the data were processed

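Total RNA from K562 cells expressing inducible U2AF1 S34F or WT (3 libraries each) was measured by stranded sequencing of 500 ng total RNA after Ribo-Zero Gold depletion, per the labels' protocols. RNA was extracted with Trizol LS and RNeasy columns and treated with DNase, per the labels. Reads were handled with Trim Galore and FastQC and the build was hg19, per the submitters' processing notes. CircRNA reads were detected with CIRI2, per the series' design text. The aligner, the CIRI2 version and the caller's settings are not given in the sources used here.

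The deposited table holds counts, not normalized values: for each circRNA and library a count of back-splice junction reads and a count of linear reads, per the file headers. It also gives a 0 or 1 flag for detection by find_circ, the circRNA type, the host gene and identifiers in CIRCpedia, circAtlas and circBase, per the file headers, all deposited by the authors. That the linear column counts reads that are not back-spliced at the same junction was read from its name and from what CIRI2 reports. A linear read may count for several circRNAs that share a splice site. No junction count equals 1, and the linear count is 0 wherever the junction count is 0. A 0 can therefore be 0 reads, 1 read or a circRNA that was not called in that library. In 63 cells a junction had back-splice reads and 0 linear reads.

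The table has 25837 rows. The 79 rows that repeated a junction's coordinates and strand were merged, which left 25758 junctions, and no library had reads in both rows. The authors' own total matched the sum of the 6 libraries in 99.27% of rows and differed in 189, so sums were taken from the libraries. Of 5940 host gene identifiers, 5929 were matched to a symbol, and all 638 genes of the fixed lists were matched to a symbol, older symbols through synonyms of the RefSeq table. Host gene counts used the 24071 junctions assigned to 1 gene; the 871 with several genes and the 816 intergenic ones were left out of them. The 32 junctions on unplaced contigs were left out of the circular to linear ratio and the chromosome sets. Coordinates are 1-based hg19 positions as deposited. No per-sample column was left unmapped.

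Junction counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr with a minimum count of 5 and a minimum total of 10, Benjamini-Hochberg adjusted p under 0.05). The standard error of a log2 fold change is its size divided by the square root of F, and positive values are higher in S34F. CPM values are junction reads scaled by the reads of the library in tested circRNAs and the TMM factor. The circular to linear ratio was tested as the interaction of read kind and genotype with a term per library, over circRNAs with both kinds of reads in all 6 libraries. Gene lists and chromosomes were tested with camera (correlation preset at 0.01), camera with an estimated correlation, and fry, from limma 3.58.1, for sets of at least 5. Measures per library were compared by exact two-sided permutation tests (scipy 1.17.1), which cannot go below p = 0.1 for 3 against 3. The number of circRNAs at equal depth is the hypergeometric expectation after thinning to the smallest library. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for the other steps.

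The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule names the 12 circRNAs with the smallest p in each direction among those past the threshold with no overlap of libraries. Where fewer than 5 passed, it names the 5 with the smallest p, said to have missed the threshold. It further names the 10 most abundant circRNAs, up to 4 hosts per list, up to 10 hosts in each direction by the same rule, and U2AF1 where listed. CircRNAs past the threshold in the ratio test, in DESeq2 or in the fit on circRNAs listed in all 6 libraries are named in addition, after their values were seen. The gene lists covered reported U2AF1 S34F splicing targets, hosts of well-studied circRNAs, regulators of circRNA biogenesis, splicing factors, chromatin modifiers, erythroid and megakaryocytic genes, innate immune genes, DNA repair, cell cycle, translation and mRNA decay, nuclear transport, ubiquitin enzymes, the region amplified around BCR and ABL1, and lymphoid and epithelial or fibroblast genes as markers of other cell types.

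The alternatives were DESeq2 size factors, library totals, DESeq2 1.42.0, limma-voom, the default filter (minimum count 10, minimum total 15), no filter, the replicate number as a block, an adjusted p under 0.1 and leaving out each library. Added after seeing the data were fits on circRNAs listed in all 6 libraries, fits without the circRNAs that WT replicate 1 alone lacked (5 or more reads in each other library), a robust dispersion, a replicate block for the ratio, and the alternatives of the exonic share for the intronic share. Pairs of libraries within a genotype differed by more than sampling noise, with chi-square per degree of freedom between 1.22 and 1.74 over the 2452 junctions listed in all 6, so no library duplicated another.

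The scripts were tested on simulated counts with 200 features changed 2-fold or 4-fold. Calls were made for 11.4% of 4-fold and 0% of 2-fold changes in the test of circRNA abundance (2563 circRNAs), 86.9% and 30.4% in the fit on circRNAs listed in all 6 libraries (1933), 77.4% and 16.5% for host genes (2016) and 82% and 23% for the circular to linear ratio (1943). Calls among features left unchanged numbered 0, 5, 8 and 9 in the same order, beside 10, 114, 87 and 105 of changed ones. For the ratio, up to 2 circRNAs changed in linear reads alone count as unchanged. The base at position -3 of the back-splice acceptor was planned as a comparison and not analysed here, since no genome of the build was used.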

Results

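Circular RNAs (circRNAs), which form when a downstream donor splice site is joined to an upstream acceptor, were counted in K562 cells, an established human line derived from chronic myeloid leukaemia. The cells carried a doxycycline-inducible copy of U2AF1, the small subunit of the factor that recognises the 3' splice site, either as wild type (WT) or with the S34F substitution, a recurrent mutation in myeloid neoplasms. Each genotype had 3 libraries, made from total RNA after ribosomal RNA depletion. Expression was induced with 250 ng/mL doxycycline for 48 h, followed by 24 h with DMSO in the continued presence of doxycycline. The comparison asked which circRNAs differ between cells expressing mutant and wild-type U2AF1. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. No back-splice junction of U2AF1 itself was listed, so the table holds no check of the genotype labels.

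The libraries held 51767, 84941 and 69647 back-splice junction reads in S34F replicates 1, 2 and 3, and 65522, 96847 and 51678 in WT replicates 1, 2 and 3. These reads fell on 25758 junctions (hg19), of which 22759 were exonic, 2183 intronic and 816 intergenic. Of these junctions, 49.6% were listed in 1 library and 2452 in all 6. The median junction had 4 reads over the 6 libraries, against 51 for the 2943 junctions that entered the test of abundance. At these depths counting error was large, since a count of 10 has an exact 95% Poisson interval of 4.795 to 18.39. Intervals cover counting error only, as the reads carry no molecular identifiers. NBAS had the most junctions of any host gene, with 83, followed by BIRC6 with 73 and PICALM with 59.

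The most abundant circRNA came from MAN1A2, a Golgi mannosidase gene (chromosome 1, 117944807 to 117963271, exonic), at 21564 ± 3266 normalised junction reads (CPM) in S34F and 17194 ± 3034 in WT (SD, n = 3). Its log2 fold change was 0.33 ± 0.18 (SE), which did not pass the test (adjusted p = 0.810, edgeR). The single-exon circRNA of HIPK3, a kinase gene (chromosome 11, 33307958 to 33309057), stood at 8695 ± 1663 CPM in S34F and 7202 ± 845 in WT. The circRNAs of CDYL (6388 ± 969 against 7061 ± 317 CPM), CAMSAP1 (7116 ± 1365 against 6779 ± 1173) and MGA (5576 ± 487 against 6064 ± 576) did not pass the test either. The other members of the 10 most abundant, from ZNF124, GSE1, SETD3, CRKL and a shorter MAN1A2 junction, had log2 fold changes between -0.45 and 0.83, none past the threshold. The ZNF124 circRNA (chromosome 1, 247319707 to 247323115) had 379, 693 and 486 reads in S34F and 601 and 346 in WT replicates 2 and 3, but 0 in WT replicate 1.

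Sequencing depth is not given, so junction reads per library do not measure circRNA output. They averaged 68785 ± 16604 in S34F and 71349 ± 23141 in WT (SD, n = 3; exact two-sided permutation p = 1.0). After thinning every library to 51678 junction reads, 8192 ± 178 circRNAs with 2 or more reads were expected in S34F and 8234 ± 452 in WT (n = 3; exact permutation p = 0.9). With 3 libraries against 3 the smallest p this test allows is 0.1. Over the 1972 circRNAs with both kinds of reads in all 6 libraries, the sums gave 2.72 ± 0.405 junction reads per 100 linear reads in S34F and 2.28 ± 0.0829 in WT (exact permutation p = 0.2, n = 3).

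By reads, the intronic share and the median span were higher in every S34F library than in any WT library, at the smallest p the design allows. Exonic circRNAs gave 92.4% ± 0.398 of junction reads in S34F and 93.0% ± 0.343 in WT, and intronic circRNAs gave 5.08% ± 0.261 and 4.51% ± 0.252 (SD, n = 3; exact permutation p = 0.1 for each). Intergenic circRNAs gave 2.56% ± 0.245 and 2.48% ± 0.228 (n = 3; exact permutation p = 0.6). The read-weighted median genomic span was 8494 bp ± 145 in S34F and 7358 bp ± 230 in WT, a difference of 0.0624 on the log10 scale (n = 3; exact permutation p = 0.1). The 10 most abundant circRNAs of each library held 5.73% ± 0.297 of its reads in S34F and 5.30% ± 0.340 in WT (n = 3, exact permutation p = 0.1). That separation was narrow, with 5.558% in S34F replicate 1 and 5.536% in WT replicate 3. WT replicate 1, at 5.46%, had 0 reads for the abundant ZNF124 circRNA, which can lower its share. Chance separates 3 libraries from 3 in 10% of groupings. The separation by type was lost when circRNAs were counted in place of reads (exact permutation p = 0.5 for the exonic and 0.4 for the intronic share, n = 3) and over the circRNAs of the abundance test (p = 0.6 and 0.3), where the exonic difference was -0.283 percentage points in place of -0.667. After Benjamini-Hochberg adjustment over the 13 measures taken per library, p was 0.26 for the exonic and intronic shares, the span and the share of the 10 most abundant.

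**Figure D1:**
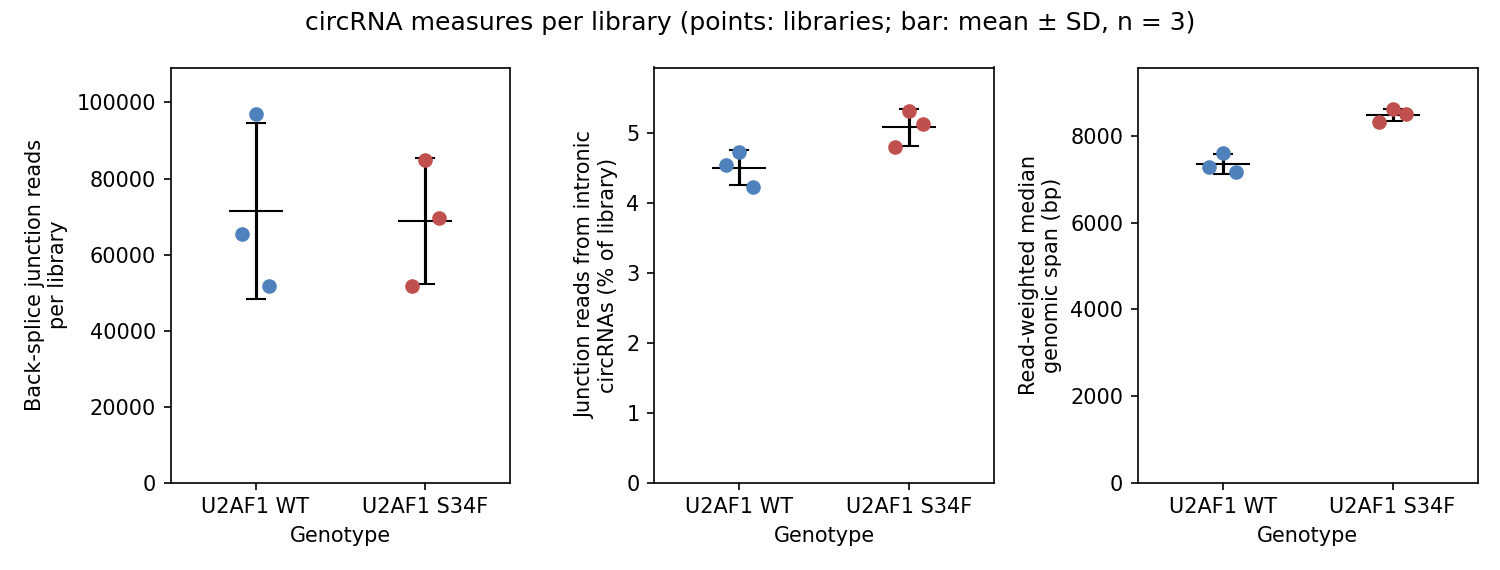
Back-splice junction reads per library, percent of junction reads from intronic circRNAs, and read-weighted median genomic span in bp, by genotype. Points are libraries and bars are means ± SD (n = 3). Junction reads overlapped between genotypes, while the intronic share (5.08% against 4.51%) and the span (8494 against 7358 bp) were higher in all S34F libraries, at the smallest p the test allows (0.1).

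The circular to linear ratio, which compares junction reads with linear reads at the same junction, differed between genotypes for 11 of 1972 circRNAs, 7 higher and 4 lower in S34F (edgeR quasi-likelihood interaction test, Benjamini-Hochberg adjusted p under 0.05). The largest increase was in a circRNA of RICTOR, the scaffold of the rapamycin-insensitive mTOR complex (chromosome 5, 38991050 to 39003724, exonic), with 10.2 ± 0.705 junction reads per 100 linear reads in S34F and 1.83 ± 0.361 in WT (SD, n = 3). Its ratio rose by a log2 fold change of 2.23 ± 0.36 (SE, edgeR adjusted p = 0.00102), while its linear reads had a log2 fold change of -0.17 ± 0.15. A circRNA of LCLAT1, a lysocardiolipin acyltransferase gene (chromosome 2, 30775358 to 30791042), had 15.9 ± 3.52 against 3.18 ± 0.716 junction reads per 100 linear reads, a log2 fold change of 2.10 ± 0.39 (edgeR adjusted p = 0.00725). A circRNA of ATG7, which encodes the activating enzyme of the autophagy conjugation systems (chromosome 3, 11399891 to 11468400), had 12.1 ± 2.77 against 3.26 ± 1.22, a log2 fold change of 1.70 ± 0.37. CircRNAs of CIZ1, a nuclear zinc finger protein gene (chromosome 9, 130931330 to 130943078; 1.67 ± 0.33), LRBA, a vesicle trafficking gene (chromosome 4, 151656409 to 151729550; 1.98 ± 0.40), UBE3D, a ubiquitin ligase gene (chromosome 6, 83667030 to 83754378; 1.85 ± 0.45) and the long noncoding RNA NEAT1 (chromosome 11, 65198239 to 65205128; 2.17 ± 0.45) rose as well.

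The circRNAs with a lower ratio in S34F came from MRPS6, a mitochondrial ribosomal protein gene, SLC25A16, a mitochondrial carrier gene, AARS1, the cytosolic alanyl-tRNA synthetase gene, and KLHL8, a Kelch-like gene. The MRPS6 circRNA (chromosome 21, 35475133 to 35497780) had 1.25 ± 0.706 junction reads per 100 linear reads in S34F and 5.49 ± 0.976 in WT (SD, n = 3), a log2 fold change of -2.22 ± 0.44 (SE, edgeR adjusted p = 0.00793). The log2 fold changes were -1.75 ± 0.39 for SLC25A16 (chromosome 10, 70246900 to 70253327), -1.64 ± 0.38 for AARS1 (chromosome 16, 70292882 to 70296427) and -1.33 ± 0.32 for KLHL8 (chromosome 4, 88116475 to 88116842). The linear reads of AARS1 had a log2 fold change of 0.73 ± 0.19 (edgeR adjusted p = 0.105), opposite to its ratio. Some of these ratios rest on few junction reads. MRPS6 had 2, 4 and 10 in S34F. In WT, LRBA had 7, 5 and 7, UBE3D 5, 5 and 8, and NEAT1 6, 6 and 4. All 11 circRNAs were exonic, and their fold changes kept their sign whichever library was left out. The number past the threshold was 4 without S34F replicate 1, 2 without S34F replicate 3 and 18 without WT replicate 3, and RICTOR passed in all 6 of these fits. The test needs reads in all 6 libraries, so circRNAs absent from a genotype were not covered.

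**Figure D2:**
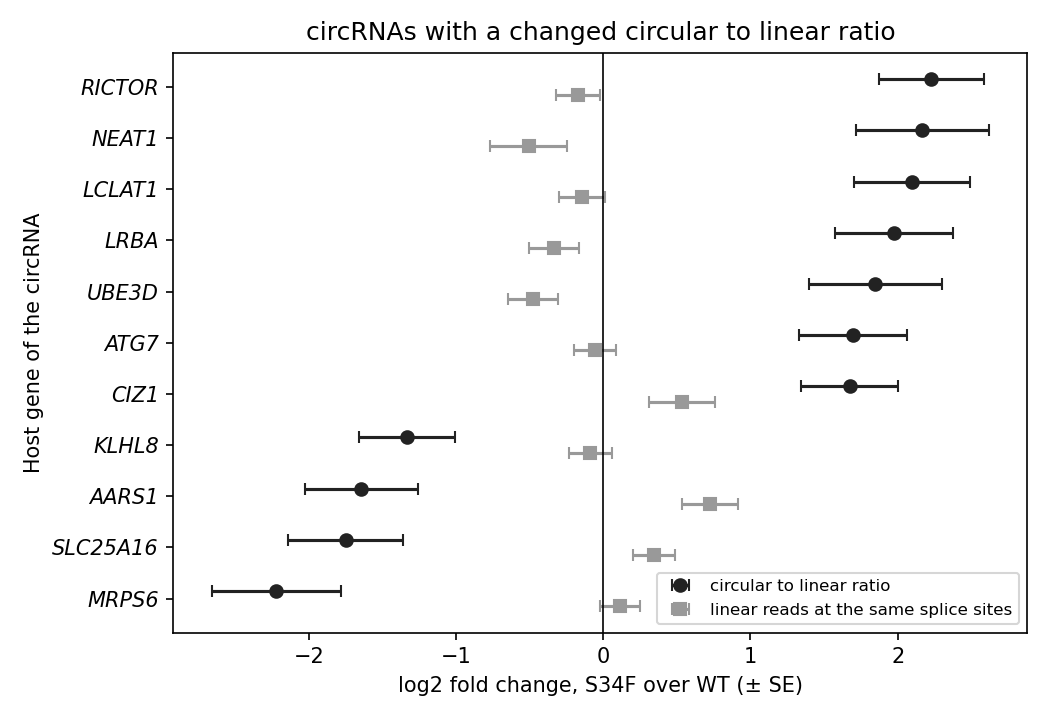
Log2 fold change, S34F over WT, of the circular to linear ratio (circles) and of the linear reads at the same splice sites (squares) for the 11 circRNAs past the threshold, named by host gene; bars are standard errors. The ratio changes run from -2.22 (MRPS6) to 2.23 (RICTOR), and the linear changes from -0.51 (NEAT1) to 0.73 (AARS1).

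**Figure D3:**
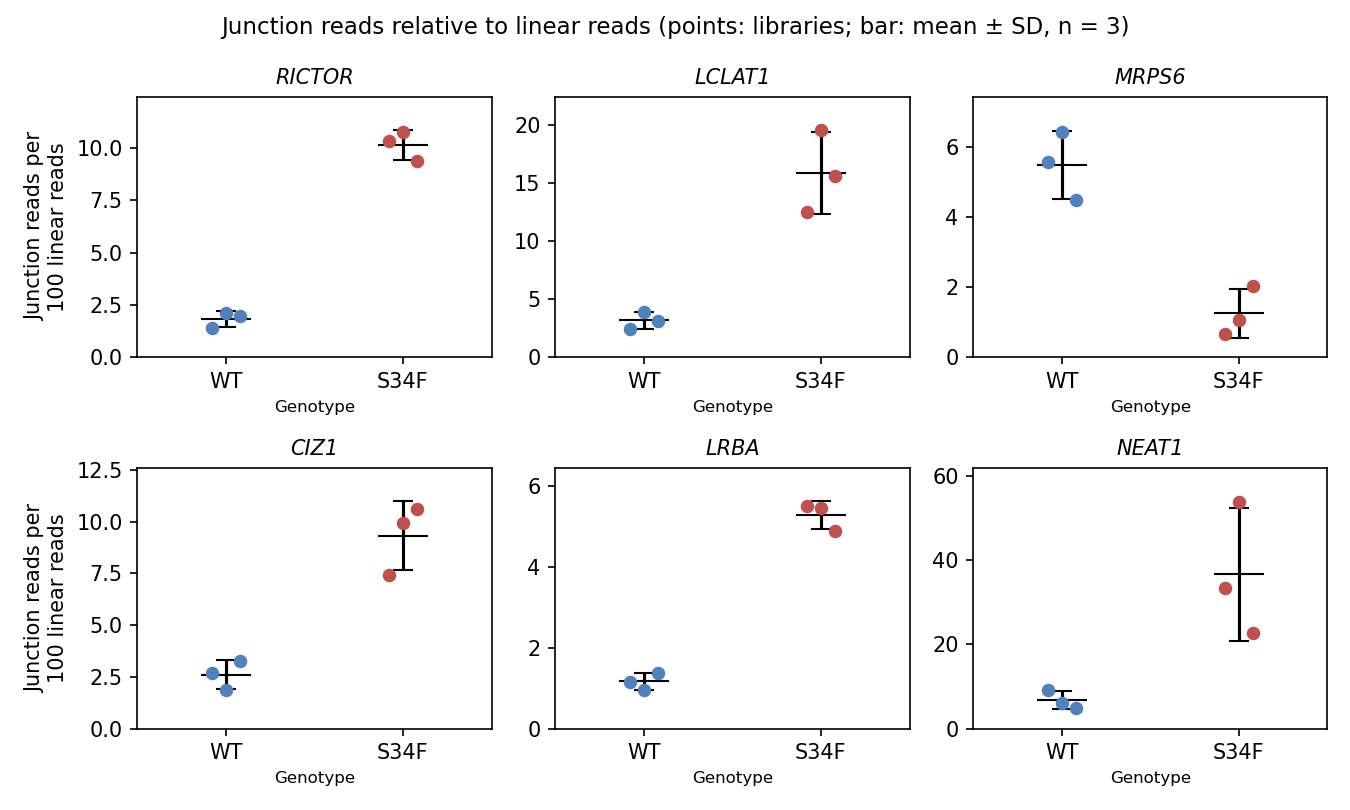
Junction reads per 100 linear reads in each library for the 6 circRNAs with the smallest p, by genotype; points are libraries and bars are means ± SD (n = 3). The RICTOR circRNA averaged 10.2 in S34F and 1.83 in WT, and the MRPS6 circRNA 1.25 and 5.49, with no overlap of libraries in any panel.

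In junction read abundance alone, 0 of 2943 circRNAs passed an adjusted p under 0.05 by edgeR. Of the 2943, 969 had no reads in at least 1 library, and the ratio test left such circRNAs out. The ratio and abundance counts therefore come from unlike sets. Restricted to circRNAs listed in all 6 libraries, abundance gave 17 of 2042 (below), in a fit chosen after seeing the data. DESeq2 called 9, limma-voom 0 and edgeR with no low-count filter 34 (21 higher, 13 lower). At an unadjusted p under 0.05, edgeR gave 111 circRNAs higher and 93 lower in S34F, 204 together, against a nominal 147.15. The 9 other splits of the 6 libraries into 3 and 3 gave between 32 and 72. Each of those splits mixes the genotypes, so a genotype difference widens the spread within groups and can lower the count. On simulated counts for this test, 11.4% of 4-fold changes and 0% of 2-fold changes were called, so changes of these sizes would mostly not be detected. The 5 circRNAs with the smallest p in each direction, which missed the threshold, included those of RICTOR (log2 fold change 2.04 ± 0.39, SE) and LCLAT1 (1.93 ± 0.36), higher in S34F, and that of HPRT1, the purine salvage enzyme gene (chromosome X, 133607388 to 133632714; -2.06 ± 0.42). An intronic ATG7 junction (chromosome 3, 11396894 to 11468400) had 12, 27 and 22 reads in S34F and 3, 5 and 0 in WT (log2 fold change 3.02 ± 0.62; adjusted p = 0.541 by edgeR and 0.0287 by DESeq2).

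The others had reads in 1 genotype alone. A junction of the pseudogene CHMP1B2P (chromosome X, 79544404 to 79565732) had 29, 71 and 11 reads in S34F, and an intergenic junction on chromosome 7 (145482154 to 145545509) had 9, 24 and 30, with 0 in every WT library. In the opposite direction, an intergenic junction on chromosome 16 (71840946 to 71958720) had 20, 36 and 23 reads in WT, a junction of CANX, which encodes an endoplasmic reticulum chaperone (chromosome 5, 179151759 to 179153760), had 27, 37 and 11, an intronic junction of ENSG00000254186 (chromosome 5, 162678726 to 162683993) had 8, 23 and 6, and a junction in SYCP2L and an overlapping gene (chromosome 6, 10894099 to 10898348) had 6, 17 and 6, with 0 in every S34F library. DESeq2 called these 6, an intergenic junction on chromosome 6 (7698219 to 7698705), the intronic ATG7 junction and RICTOR. No fold is given against a genotype at 0, because a 0 in the table can also be a junction that was not called. The junction of CANX and the intergenic ones on chromosomes 7 and 16 were not found by find_circ.

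WT replicate 1 lacked many circRNAs that the other libraries held. Of 571 junctions with 10 or more reads in each of the 5 other libraries, 150 (26.3%, 95% Wilson interval 22.8% to 30.03%) had none in WT replicate 1, while the same count for the other libraries was between 1 and 13. The common dispersion of the edgeR fit was 0.222, against 0.137 without the circRNAs that WT replicate 1 alone lacked and 0.164 without that library, both with 0 calls. It was 0.0394 when only circRNAs listed in all 6 libraries were tested. In that fit, an alternative chosen after seeing the data, 17 of 2042 circRNAs passed, 9 higher and 8 lower in S34F. Of the 17, 7 were also among the 11 with a changed ratio. The ratio uses the same junction reads, so this overlap is not independent support. The higher ones of the 17 were CIZ1 (log2 fold change 2.25 ± 0.31, SE), RICTOR (2.03 ± 0.36), GRB10, a receptor adaptor gene (2.27 ± 0.50), EVC2 (2.20 ± 0.55) and LCLAT1 (1.92 ± 0.41). LRBA (1.64 ± 0.45), ATG7 (1.62 ± 0.38), the Fanconi anaemia ubiquitin ligase gene FANCL (1.54 ± 0.39) and KANSL1, of a histone acetyltransferase complex (0.97 ± 0.26), were higher too.

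The lower ones in that fit were HPRT1 (-2.08 ± 0.55), MRPS6 (-2.06 ± 0.45), an intergenic junction on chromosome 16 (18234158 to 18275735; -1.90 ± 0.49), the deubiquitinase gene USP45 (-1.90 ± 0.52), the Fanconi anaemia gene FANCB (-1.66 ± 0.43), PAK1IP1 (-1.56 ± 0.40), KLHL8 (-1.42 ± 0.30) and VAPA, an endoplasmic reticulum membrane protein gene (-1.05 ± 0.25). VAPA libraries overlapped between genotypes, at 1575 ± 822 CPM in S34F and 3284 ± 1170 in WT (SD, n = 3). Leaving out 1 library gave 3 calls without S34F replicate 1, 9 without S34F replicate 3 and 6 without WT replicate 2. It gave between 15 and 22 for the other 3 libraries, including 22 without WT replicate 1. Restricting the fit to circRNAs seen in every library excludes those that one genotype lost. Standard errors in this fit do not closely follow each circRNA's own spread. CIZ1 had 42, 49 and 119 reads in S34F, with an SE of 0.31 in this fit and 0.57 in the main fit. GSE1 (SD of 3000 CPM in S34F and 3546 in WT) had 0.24, against 0.45 in the main fit. CDYL (SD of 969 and 317 CPM) had 0.22, against 0.18 in the main fit.

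**Figure D4:**
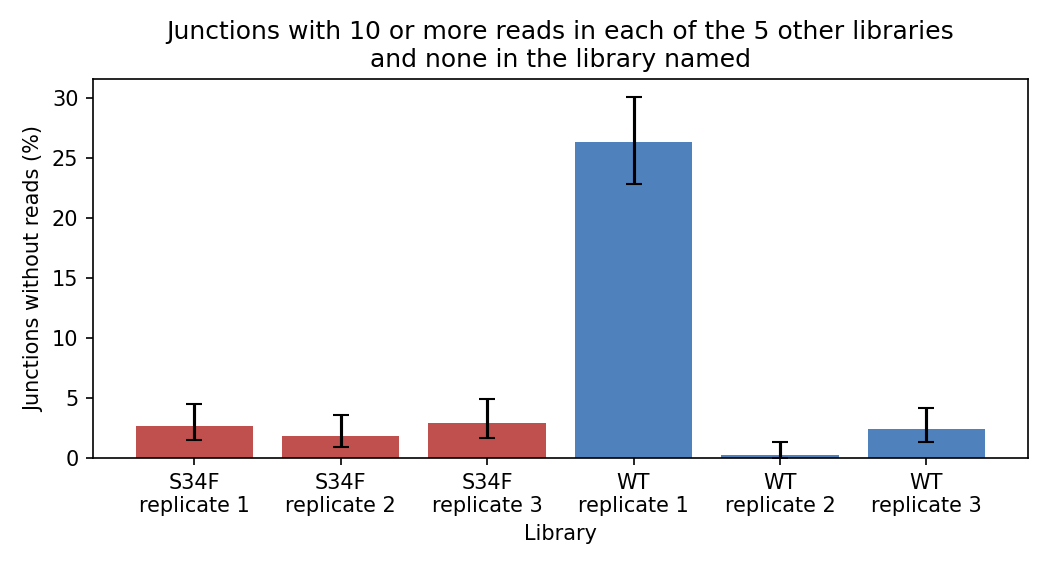
Percent of junctions with 10 or more reads in each of the 5 other libraries that had 0 reads in the library named; bars above and below are 95% Wilson intervals. WT replicate 1 lacked 26.3% of such junctions, while the other libraries lacked between 0.24% and 2.92%.

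Summed over the circRNAs of each host gene, 0 of 2206 host genes passed by edgeR (80 higher and 81 lower at an unadjusted p under 0.05), while DESeq2 called 4, limma-voom 0 and edgeR with no low-count filter 20. The 5 hosts with the smallest p in each direction missed the threshold. Among those higher in S34F were ATG7, with 1393 ± 300.4 CPM in S34F and 479.8 ± 44.0 in WT (SD, n = 3; log2 fold change 1.53 ± 0.26, SE), and CHMP1B2P, with 29, 76 and 11 reads in S34F and 0 in each WT library. LCLAT1 (1.64 ± 0.29), the long noncoding RNA MALAT1 (1.58 ± 0.32) and CIZ1 (1.97 ± 0.47) followed in the same direction. Lower in S34F by the same rule was ENSG00000254186, with 10, 35 and 6 reads in WT and 0 in S34F. ANO5 (-3.88 ± 0.85), MRPS6 (-1.82 ± 0.44), SMCHD1, a chromatin protein gene (-1.36 ± 0.37) and the nucleoporin gene NUP155 (-1.55 ± 0.44) were lower as well. ANO5 had 0, 3 and 0 reads in S34F and 14, 17 and 18 in WT, so its fold rests on S34F counts near 0. NUP155 had 19, 23 and 17 reads in S34F and 80, 104 and 17 in WT, so the difference came from WT replicates 1 and 2. DESeq2's 4 were ATG7, LCLAT1, CHMP1B2P and ENSG00000254186. Host sums hold no reads for the junctions that WT replicate 1 lacked. With counts summed over circRNAs listed in all 6 libraries, edgeR called 15 host genes.

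Of 15 gene lists fixed before the data were examined, 13 had at least 5 tested host genes. None of the 13 shifted as a group in a common direction (camera, lowest adjusted p = 0.904). Camera with an estimated correlation gave a lowest adjusted p of 0.938, and fry 0.342. Changes in both directions within a list are not covered by these results. For such changes, fry gave an unadjusted mixed p from 2.5e-05 (ubiquitin enzymes) to 0.723 (erythroid and megakaryocytic genes). It was 0.000219 for the reported U2AF1 S34F targets. This mixed test does not compare a list with the other host genes, so it cannot show that a list stands out. Of the 15 tested hosts reported elsewhere as splicing targets of U2AF1 S34F, 7 had a positive log2 fold change and 1, ATG7, passed when adjusted over the list alone (adjusted p = 0.00211, edgeR), with 0 over all genes tested. In this list EZH2, a histone methyltransferase gene, had -0.69 ± 0.24 (SE), MACROH2A1, a histone variant gene, -1.96 ± 0.90 and DEK 0.90 ± 0.50. MACROH2A1 had 3, 4 and 0 reads in S34F and 6, 11 and 12 in WT. DEK had 119, 237 and 135 reads in S34F and 21, 199 and 74 in WT, the fewest in WT replicate 1. The list's median (-0.01) and mean (-0.13) were negative while camera's direction was up. For the other 12 lists the count adjusted over the list alone was 0. With host counts from circRNAs listed in all 6 libraries it was 2 for these targets, 3 for chromatin modifiers, 2 for translation and mRNA decay, 1 for ubiquitin enzymes and 0 for the other 6 lists tested, and no list passed as a group.

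Of 17 tested spliceosome and splicing factor genes, 7 had positive values, among them SON (1.82 ± 0.57) and the helicase gene DDX46 (1.39 ± 0.51), while the splicing kinase genes SRPK2 (-1.49 ± 0.55) and SRPK1 (-0.68 ± 0.32) were negative. Of 12 regulators of circRNA biogenesis, export and decay, 4 were positive, while ILF2, a double-stranded RNA-binding factor gene, had -1.08 ± 0.39. EIF2AK2, the RNA-activated kinase gene, had -3.12 ± 1.14. That value rests on 1 junction with 0, 0 and 2 reads in S34F and 8, 10 and 4 in WT. Of 35 hosts of well-studied circRNAs, 15 were positive, with ASXL1 at -0.63 ± 0.20, MAN1A2 at 0.35 ± 0.15 and FAT1 at -0.60 ± 0.27; the list's mean (0.03) differed in sign from its median (-0.07) and its test. Of 50 chromatin modifier genes, 24 were positive, including the demethylase gene KDM1A (0.50 ± 0.22), while ASXL1 and EZH2 were the lowest in p. Of 33 DNA repair genes, 14 were positive, with RIF1 at 0.98 ± 0.42, ATM at -0.79 ± 0.34 and USP1 at -0.96 ± 0.43. Of 45 cell cycle and centrosome genes, 28 were positive, with the phosphatase gene CDC14A at 1.44 ± 0.41 and the nuclease and helicase gene DNA2 at -0.50 ± 0.20.

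Of 38 translation and mRNA decay genes, 20 were positive, among them EIF4G3 (0.68 ± 0.23) and CNOT2 (0.91 ± 0.32), while NOL10 had -1.44 ± 0.49. Of 26 nuclear transport genes, 9 were positive, with NUP155, whose WT replicate 3 had no more reads than any S34F library, the lowest in p and IPO11 at -0.47 ± 0.24. Of 49 ubiquitin ligase and deubiquitinase genes, 19 were positive, with UBR1 at -1.13 ± 0.38 and USP22 at -1.79 ± 0.67. The 5 innate immune genes had 2 positive values, with TANK at -0.84 ± 0.44 and TRAF3 at 1.09 ± 0.70. The 6 erythroid and megakaryocytic genes had 3 positive values, with the transferrin receptor gene TFRC at 0.28 ± 0.23 and PICALM at 0.23 ± 0.22. The 5 genes of the region amplified around BCR and ABL1 had 3 positive values, with NUP214 at 0.49 ± 0.28 and CABIN1 at -0.65 ± 0.52. The lists of lymphoid and of epithelial and fibroblast genes, which mark other cell types, had 0 tested hosts each, with 2 and 3 genes holding any junction.

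By chromosome, none of 23 sets of circRNAs shifted in a common direction (camera, lowest adjusted p = 0.920). Camera with an estimated correlation gave a lowest adjusted p of 0.942, and fry 0.819. Chromosome 2 had the highest median log2 fold change, 0.17 over 277 circRNAs, and chromosome X the lowest, -0.15 over 54. Adjusted over a chromosome alone, 1 circRNA passed on chromosome 5, 1 on chromosome 16 and 2 on chromosome X, with 0 over all circRNAs tested. For chromosomes 7, 10, 14, 15, 20, 21, 22 and X the median, the mean and camera's direction differed in sign.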

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

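The linear reads at junctions on unplaced contigs, which were left out of the circular to linear ratio, stood out as a signal outside the main measurement that was higher in an S34F library than in any WT library. They made up 94.9% of the linear reads listed for S34F replicate 1 (95% Wilson interval 94.92% to 94.93%), against 52.2%, 21.1% and 0.0432% in WT replicates 1, 2 and 3. Of the 80761693 such reads in S34F replicate 1, 80761389 lay at junctions of 1 contig, GL000220.1, which holds 21 of the 32 junctions on unplaced contigs. S34F replicates 2 and 3 stood at 13.1% and 0.0227%. No junction of GL000220.1 was listed in S34F replicate 3 or WT replicate 3. Linear reads are given only where a junction is listed, so these libraries' shares do not show that such reads were few. A linear read may count for several junctions, so the Wilson interval understates the error. On average the share was 36.001% ± 51.4 in S34F and 24.5% ± 26.2 in WT (SD, n = 3, exact permutation p = 0.9). These means include S34F replicate 3 and WT replicate 3, so they do not settle whether the genotypes differ.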

How the results depend on the processing

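The setting that used only circRNAs listed in all 6 libraries, those without the circRNAs that WT replicate 1 alone lacked or with a robust dispersion, the block for the ratio and the alternatives for the intronic share were chosen after seeing the data. For the abundance of circRNAs, 14 of 17 alternatives gave the main count of 0. DESeq2 called 9 (5 higher, 4 lower) and 4 host genes. With no low-count filter edgeR called 34 (21 higher, 13 lower) and 20 host genes. With only circRNAs listed in all 6 libraries it called 17 (9 higher, 8 lower) and 15 host genes, with a common dispersion of 0.0394 in place of 0.222. The cause was not tested for any of these. Leaving out each library gave 0 to 0 circRNAs and host genes. The 11 circular to linear calls ranged from 2 to 18 when a library was left out, for which the cause was not tested, and were 11 with a minimum of 10 junction reads in total. No gene list or chromosome shifted in a common direction in any alternative, the list test on circRNAs listed in all 6 libraries included. Leaving out each library gave 0 to 0.

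The difference in junction reads, -2564, ran from -12400 to 10180 when a library was left out, turning positive without S34F replicate 1 or WT replicate 2. The difference in circRNAs at equal depth, -41.5, ran from -213.2 to 214.4, turning positive without S34F replicate 2 or WT replicate 1. Leaving out a library, the difference in exonic share stayed between -0.865 and -0.437 percentage points and that in intronic share between 0.443 and 0.720. Counting circRNAs, the exonic difference was -0.444 (p = 0.5, exact permutation test) and the intronic 0.311 (p = 0.4). Over the circRNAs of the abundance test they were -0.283 (p = 0.6) and 0.372 (p = 0.3), and over those listed in all 6 libraries -0.262 and 0.245 (p = 0.1 each, all exact permutation tests). When a library was left out the span difference stayed between 0.0570 and 0.0700 on the log10 scale. These tests cannot pass 0.05 in this design, so they say nothing of stability.

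Replicate numbers are shared by both genotypes, but the labels do not say what they mark. Deviations of same-numbered libraries correlated at 0.056, 0.114 and 0.082 over circRNAs listed in all 6, and each library correlated best with its own number, a hint from the data. With the replicate number as a block, 58 ratios passed in place of 11, 0 circRNAs, host genes, lists and chromosomes passed, and the paired difference in junction reads was -2564.

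With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split and the highest of the others gave 0 and 1 circRNAs, 0 and 0 host genes, 17 and 1 circRNAs listed in all 6 libraries, 11 and 0 ratios, and 0 and 0 for both lists and chromosomes. As many calls came from 10 of the 10 splits for circRNA abundance, host genes, lists and chromosomes, and from 1 for the others. Splits other than the real one mix the genotypes, which can lower their counts, so they are not a clean reference. Depth limits the precision of each circRNA, as the median tested one had 51 reads in total over the 6 libraries. Depth and the spread between libraries were not separated as limits of the abundance test, which recovered 11.4% of simulated 4-fold changes, against 86.9% in the fit on circRNAs listed in all 6 libraries. The acceptor base at -3 and its alternatives were not run.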

Other observations

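The tests of the WT replicate 1 gaps, of database listing, of the loss estimate in other splits and of the size kept by the ratio changes were chosen after the results were seen, and the criterion of the acceptor test was reworded after its value was known. Other junctions of the hosts with a called ratio gave a mixed picture. RICTOR had a second tested circRNA with the same donor and another acceptor (chromosome 5, 38991050 to 39021238), whose ratio had a log2 fold change of -0.09 ± 0.32 (SE) beside 2.23 ± 0.36 for the called one. SLC25A16 likewise had 0.35 ± 0.48 for its second circRNA (chromosome 10, 70246900 to 70266475) beside -1.75 ± 0.39. The second LRBA circRNA with the same acceptor (chromosome 4, 151682934 to 151729550) had -0.23 ± 0.44, a further one (chromosome 4, 151509199 to 151520283) had 0.63 ± 0.52, and the other 3 KLHL8 circRNAs, all with the acceptor of the called one, had between -0.42 and 0.38. The second circRNAs of AARS1 (chromosome 16, 70294946 to 70296427; -0.90 ± 0.44, unadjusted p = 0.0496) and UBE3D (chromosome 6, 83728691 to 83754378; 0.71 ± 0.50), each with the acceptor of the called one, had its direction. In ATG7 the second circRNA with the same acceptor (chromosome 3, 11399891 to 11421526) had 1.29 ± 0.43, and in LCLAT1 the second circRNA with the same donor (chromosome 2, 30748452 to 30791042) had 1.19 ± 0.52, both at an unadjusted p under 0.05.

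Since U2AF1 acts at acceptors, a hypothesis was that the change of a circRNA follows its acceptor. Over 190 disjoint pairs of circRNAs that shared the acceptor, the median absolute difference of the log2 ratio change was 0.48, against 0.50 over 141 pairs that shared the donor and 0.57 over 986 random pairs. The acceptor and donor pairs did not differ detectably (permutation p = 0.693, two-sided), so the hypothesis stays open. Pairs of circRNAs are not independent replicates, and pairs with a shared site also share linear reads.

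For the 11 circular to linear calls, the median size of the linear log2 change was 0.335 beside 1.85 for the ratio, which argues against linear reads as the whole cause. The linear change had the opposite sign to the ratio in 9 of the 11, and 4 of the 11 had an unadjusted linear p under 0.05 (edgeR). Linear reads are the divisor of the ratio, so selection on the ratio favours opposite signs. These counts therefore cannot show that linear reads changed. Linear reads may add to some changes, such as AARS1, with 0.73 for linear reads and -0.88 for junction reads. Of the 11, 5 stayed past the threshold in at least 4 of the 6 fits that left out a library, but only RICTOR in all 6. Each of the other 10 missed it without at least 1 library, in fits that also have less power. Every call kept at least 82.7% of its log2 change when a library was left out. The calls passed a test that favours agreement between libraries, so this says little of whether 1 library sets the size. A difference between the engineered cells that is not due to the mutation stays open, as does an effect of the mutation, since the design does not separate them.

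In WT replicate 1, 150 of 571 abundant junctions had no reads. Its depth of 65522 junction reads does not account for this, since 0.00167 such junctions would be expected. Loss of whole splice sites is not seen, with 6 sites of 76 missing all of their junctions and 11 as the highest of 1000 random reassignments. Absence of the host transcript is not seen either, since 89.5% of the 143 missing junctions with 1 host gene (128) had a host with another junction called in that library. A step in the calling of this library that drops single junctions stays open and was not tested, and no biological explanation other than the absence of the host was tested.

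There were 16 junctions with 5 or more reads in every library of one genotype and none in the other, 5 in S34F alone and 11 in WT alone. The highest count for another split was 12, with S34F replicates 1 and 3 and WT replicate 3 on one side, and 1 of the 10 splits reached the real count, too few splits for a share under 0.05. Independent loss of calls in single libraries would give 0.17, but the same estimate gives 2.09 for the other 9 splits, where 42 were seen, so it fails where genotype plays no part and lost calls stay open. Of the 16, 75% were listed in a circRNA database, below the 93.75% to 100% that held the middle 95% of random draws from the same range of reads, and 40 of 42 junctions of the same kind in other splits were listed (Fisher's exact test, p = 0.0434). Sequence or rearrangements private to the cells of one genotype may account for the 4 unlisted ones. These lie in CANX, MGC4859 and the intergenic regions of chromosomes 7 and 16. None of the 4 was found by find_circ, which found 56.25% of the 16, and whether they are circRNAs was not tested. Private sequence is confounded with genotype, and lost calls and an effect of the mutation stay open.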
